A study of Mus musculus with 2 samples.

How the data were processed

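H3K4me3 ChIP-seq was performed on intestine pooled from mouse embryos of strain B6NCrl at embryonic day 16.5. Per the labels, both samples are biological replicates of 1 group, of mixed sex, with library fragments of 300 to 500 bp. Replicate 2 came from 41 embryos. The labels name a possible control experiment, whose data were not used here. The authors deposited 4 peak lists on mm10: one for each replicate, one for both replicates pooled and one of replicated peaks. Per the deposited description files, replicate 1's list and the pooled list were made from filtered alignments together with 2 further undescribed files, and replicate 2's list from its alignments and 1 such file. The aligner, the peak caller, its threshold and the rule for keeping a replicated peak are not given in the sources used here. Such differences in input can shift signal and peak number between replicates, and broad marks can be split into several peaks by a caller that reports narrow ones.

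The lists have the columns of the narrowPeak format. The signal value of each peak is the enrichment as the authors' caller gave it, with scaling and control not stated. The deposited -log10 p and -log10 q values grow with depth and start at 2.03 (p) and 0.20 (q), so the lists hold weak peaks: 92.4% of replicate 1's and 89.5% of replicate 2's peaks had -log10 q of at least 2, against 99.5% of the replicated peaks. The deposited display score, a whole number scaled within each list, was not used, nor was the summit position. Signal values were used to describe and rank peaks within a list, and the replicates' values were set side by side to give the spread of each gene and the ratio between the replicates. All 27922 replicated peaks had the same interval and signal as a pooled peak. Of these, 25514 were covered over at least 50% of their length by both replicates' own peaks and 2408 were not, so the replicated list admits more than that overlap of the own lists. Read depth is unknown, since peak lists hold no counts, and no interval that needs it is given.

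Genes were taken from GENCODE M21 on GRCm38, the assembly of mm10, and sequence from the RefSeq copy of the same assembly; no peak lay beyond a chromosome end. A promoter was the window of 1000 bp either side of any transcription start of a protein-coding transcript on chromosomes 1 to 19, X and Y, which gave 21853 genes. A gene was marked where a replicated peak overlapped a window by at least 1 bp. Where several genes share a peak, each was counted, and 2471 marked genes (16.8%) shared all their peaks with another gene's window. Promoter signal was the largest signal value among a replicate's own peaks at the promoter. Domains were replicated peaks joined at gaps under 1000 bp, 22516 in all, and the widest 5% of those at promoters were broad. The CpG ratio was the count of CpG times the window length over the square of the mean of the C and G counts, the highest over a gene's windows, with classes bounded at 0.35 and 0.65.

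The 29 gene lists, their tests and the rule for named genes were fixed in advance. Named genes were a fixed set of anchor genes and, per list, the 2 marked members of highest signal, the marked member of lowest signal, up to 2 unmarked members in alphabetical order and up to 2 members marked in one replicate only, as well as the 10 genes of highest signal and the 10 of widest domain. Exceptions are stated where they occur. Of the listed symbols Pla2g2a (Paneth) was not matched, and Cblif was matched as Gif. List marking and broad domains were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. List medians of signal were placed among 10000 random lists (seed 1). Overlap and position were compared with 20 shuffles of the intervals within chromosomes outside assembly gaps. With 1 group of 2 samples there was no test between groups, no check of outliers and no replicate block.

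Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1 shuffled intervals. The list test was tried on simulated lists of 20 genes drawn from the 21853 genes, 100 of each kind. It called 0% of lists at the background share, 90% of lists marked at 95% and 100% of lists marked at 20%. A list of 10 genes or fewer has less power than that. Alternatives covered the promoter window, the start used, stricter peak thresholds, the pooled list, the overlap required, the way signal was summed, the joining of peaks, the width limit and each replicate alone. Peaks on scaffolds outside the assembled chromosomes were left out of the gene counts.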

Results

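H3K4me3, trimethylation of lysine 4 of histone H3, marks the promoters of active genes and of many genes held ready for use. It was profiled by ChIP-seq in the intestine of mouse embryos of strain B6NCrl at embryonic day 16.5, when the villi are forming and the gut wall holds epithelium, mesenchyme, smooth muscle, enteric neurons and vessels. There was 1 group of 2 biological replicates, each a pool of embryos of both sexes. Replicate 2 was made from 41 embryos, and the number for replicate 1 was not given. With no second tissue, age or treatment, the comparisons were between the replicates and between groups of genes within this tissue. Each replicate had its own peak list, with 34101 peaks in replicate 1 and 34565 in replicate 2, and the authors deposited a list of 27922 replicated peaks, whose rule is not given in the sources used here. Peak lists carry no read counts, so the depth of each library is unknown. Promoter signal below is the authors' peak signal value, the largest at a gene's promoter in each replicate's own list, given as mean ± SD (n = 2).

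Genes of the absorptive and stem cell epithelium, the smooth muscle and the mesenchyme of the gut were marked at nearly all of their promoters. Of 21853 protein-coding genes, 14714 (67.3%) had a replicated H3K4me3 peak within 1000 bp of a transcription start. Among 29 gene lists chosen before the data were examined, 9 were marked more often than other genes and 9 less often. Calls are from Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 29 lists at a threshold of 0.05. Genes are not replicates, so these tests describe the lists in these 2 pools of tissue.

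All 26 intestinal epithelial transcription factors were marked, against 67.3% of other genes (adjusted exact p = 0.00027). Cdx2, a homeobox factor that sets intestinal identity, had a promoter signal of 32.8 ± 1.1, and its relative Cdx1 had 21.5 ± 3.0. Hnf4a, a nuclear receptor of the epithelium, had 22.2 ± 2.9. The highest values in the list were 54.1 ± 7.4 at Foxa3, whose peak also meets the promoter window of the neighbouring gene Sympk, and 52.2 ± 8.1 at Tcf7l2, the nuclear effector of Wnt signalling. The lowest was 5.56 ± 0.34 at Ehf. Of the intestinal stem and progenitor genes, 22 of 23 were marked (adjusted exact p = 0.0061), among them the Wnt target Lgr5 with 33.4 ± 6.5 and Lrig1, an inhibitor of growth factor receptors, with 56.5 ± 2.6. Olfm4 was the unmarked member.

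Genes of absorptive cells were marked too, at lower signal. Of 27 enterocyte genes, 24 were marked (88.9%, adjusted exact p = 0.022). Vil1, a structural protein of the brush border, had 16.4 ± 4.6 and the fatty acid carrier Fabp2 had 9.98 ± 4.15. The highest values were 29.6 ± 3.1 at Mttp, needed for lipoprotein assembly, and 29.0 ± 1.1 at Anpep, a brush border peptidase. The disaccharidase Sis and the fructose transporter Slc2a5 were unmarked, as was Treh, a disaccharidase named here after its values were seen. Slc2a5 had a peak only in replicate 1's own list. The enterocyte call ended with a window of 500 bp (85.2%), with the gene's 5' end only (74.1%), with -log10 q of at least 10 (77.8%), with signal of at least 4 (81.5%) and with overlap of at least 200 bp (85.2%).

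Secretory lineages were not called higher. Goblet cell genes were marked at 9 of 14 promoters (adjusted exact p = 0.84), from 43.3 ± 0.5 at Creb3l1 down to 4.25 ± 0.80 at Tff3, and the mucin gene Muc2 had a peak in replicate 2's own list only. Among promoters of low CpG ratio, 5 of 9 goblet genes were marked, against 17.1% of other genes, without a call (adjusted exact p = 0.089). The low-ratio counts were 0 of 4 for enteroendocrine and 1 of 6 for tuft genes. Enteroendocrine genes were marked at 15 of 23 (adjusted exact p = 0.86), with 27.2 ± 3.3 at Isl1 and 6.18 ± 0.07 at Neurog3, the factor that starts that lineage. Tuft cell genes were marked at 4 of 10 (adjusted exact p = 0.12), led by Dclk1 with 24.8 ± 3.6 and Ptgs1 with 24.5 ± 0.7. Still uncalled, the goblet share lay above that of other genes with a window of 2000 bp (85.7%), with the pooled list and without replicate 1 (78.6% each), and with peaks that meet no other gene's promoter (64.3%). So did the enteroendocrine share with the pooled list and without replicate 2 (69.6% each), with the gene's 5' end only and with peaks that meet no other gene's promoter (65.2% each). None of the 10 Paneth cell genes was marked (adjusted exact p = 0.00010), including Lyz1 and Defa17. All 10 have promoters of low CpG ratio, a class in which 17.2% of the other genes were marked. Within that class the Paneth list was not called (adjusted exact p = 0.82), although 0 of 10 is the lowest possible share. The test within the class could not have called a list of this size lower. It leaves open whether CpG content accounts for the absence of marking.

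In the gut wall, all 15 smooth muscle genes (adjusted exact p = 0.0080) and all 24 gut mesenchyme genes (adjusted exact p = 0.00036) were marked. In the smooth muscle list, signal ranged from 59.1 ± 5.7 at Srf, a general regulator of muscle genes, to 6.72 ± 0.73 at the contractile gene Cnn1, and was 11.9 ± 1.3 at Acta2. In the mesenchyme list, the Hedgehog receptor Ptch1 had 44.0 ± 1.4, the Hedgehog effector Gli3 41.1 ± 5.7, Foxf1 32.2 ± 2.2, Foxl1 20.3 ± 0.4 and the matrix gene Dcn 5.74 ± 0.56. Signalling ligands and antagonists were marked at 27 of 28 promoters (adjusted exact p = 0.00097). Of the epithelial Hedgehog ligands, Ihh had 36.8 ± 0.04 and Shh 23.1 ± 4.3. Fgf7 was the unmarked ligand, with a peak in replicate 1's own list only.

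Markers of the other cell types present in the gut were marked in part. Enteric nervous system genes were marked at 18 of 24 promoters (adjusted exact p = 0.58). Ret, the receptor of neural crest cells that colonise the gut, had 30.2 ± 12.1, with replicate values of 38.7 and 21.6. Phox2b had 7.03 ± 0.10 and Sox10 6.23 ± 0.88. Endothelial genes were marked at 17 of 20 (adjusted exact p = 0.13), from 36.9 ± 5.6 at Egfl7 to 4.04 ± 0.11 at Robo4, with 6.81 ± 0.50 at Pecam1. Mesothelial genes were marked at 6 of 9 (adjusted exact p = 1) and erythroid genes at 6 of 15 (adjusted exact p = 0.067), the latter led by Klf1 with 43.1 ± 2.9. Immune genes were marked less often, at 9 of 22 promoters (adjusted exact p = 0.021). Of these, 17 have a low CpG ratio, and in that class 5 of 17 were marked, against 17.1% of other genes (adjusted exact p = 0.77). Their highest values were at Id2 and Ikzf1, with 39.4 ± 1.5 and 37.3 ± 4.4, and the lowest at Spi1, with 2.27 ± 0.49. Ptprc, which encodes the leukocyte surface protein CD45, had a peak in each replicate's own list (2.83 ± 0.12) and none in the replicated list. The immune call ended with a window of 2000 bp (45.5% marked), with the pooled list (54.5%), without replicate 1 (54.5%) and without replicate 2 (50%). It also ended with peaks that meet no other gene's promoter. There 40.9% were still marked, below other genes, whose own share had fallen.

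Lists of other organs were mostly marked less often. Marked promoters numbered 2 of 14 for stomach (adjusted exact p = 0.00027), 3 of 20 for liver (adjusted exact p = 2.0e-05), 3 of 12 for kidney (adjusted exact p = 0.0068), 4 of 18 for skeletal muscle (adjusted exact p = 0.00036), 4 of 13 for keratinocyte (adjusted exact p = 0.022) and 3 of 20 for germ line (adjusted exact p = 2.0e-05). Of 1134 olfactory receptor genes, 4 were marked. Alb, Afp, Ddx4 and Atp4a had no replicated peak. Several marked members were regulators at low signal, such as Sox2 of the stomach list with 13.6 ± 1.9 and Myod1 of the muscle list with 3.0 ± 0.47. Others had no peak of their own: Mylpf, Actn3 and Apoh shared every peak with the promoter windows of Tbc1d10b, Zdhhc24 and Prkca. The kidney call ended without replicate 1 (41.7%), and the kidney (25%) and keratinocyte (30.8%) calls ended with peaks that meet no other gene's promoter. The remaining lists were not called: 9 of 18 for pancreas (adjusted exact p = 0.15), 5 of 13 for lung and thyroid (adjusted exact p = 0.056), 9 of 18 for cardiac muscle (adjusted exact p = 0.15) and 20 of 23 for brain (adjusted exact p = 0.067). Signal was 13.3 ± 1.1 at Pdx1, 9.67 ± 0.02 at Nkx2-1, 4.44 ± 0.11 at Nkx2-5 and 9.82 ± 0.20 at Foxg1, the last at a peak shared with Gm43517. All 20 housekeeping genes (adjusted exact p = 0.0012) and all 21 cell cycle genes (adjusted exact p = 0.00087) were marked, with 51.9 ± 7.6 at Actb and 48.9 ± 14.5 at Gapdh. The housekeeping call ended with peaks that meet no other gene's promoter (80%).

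**Figure D1:**
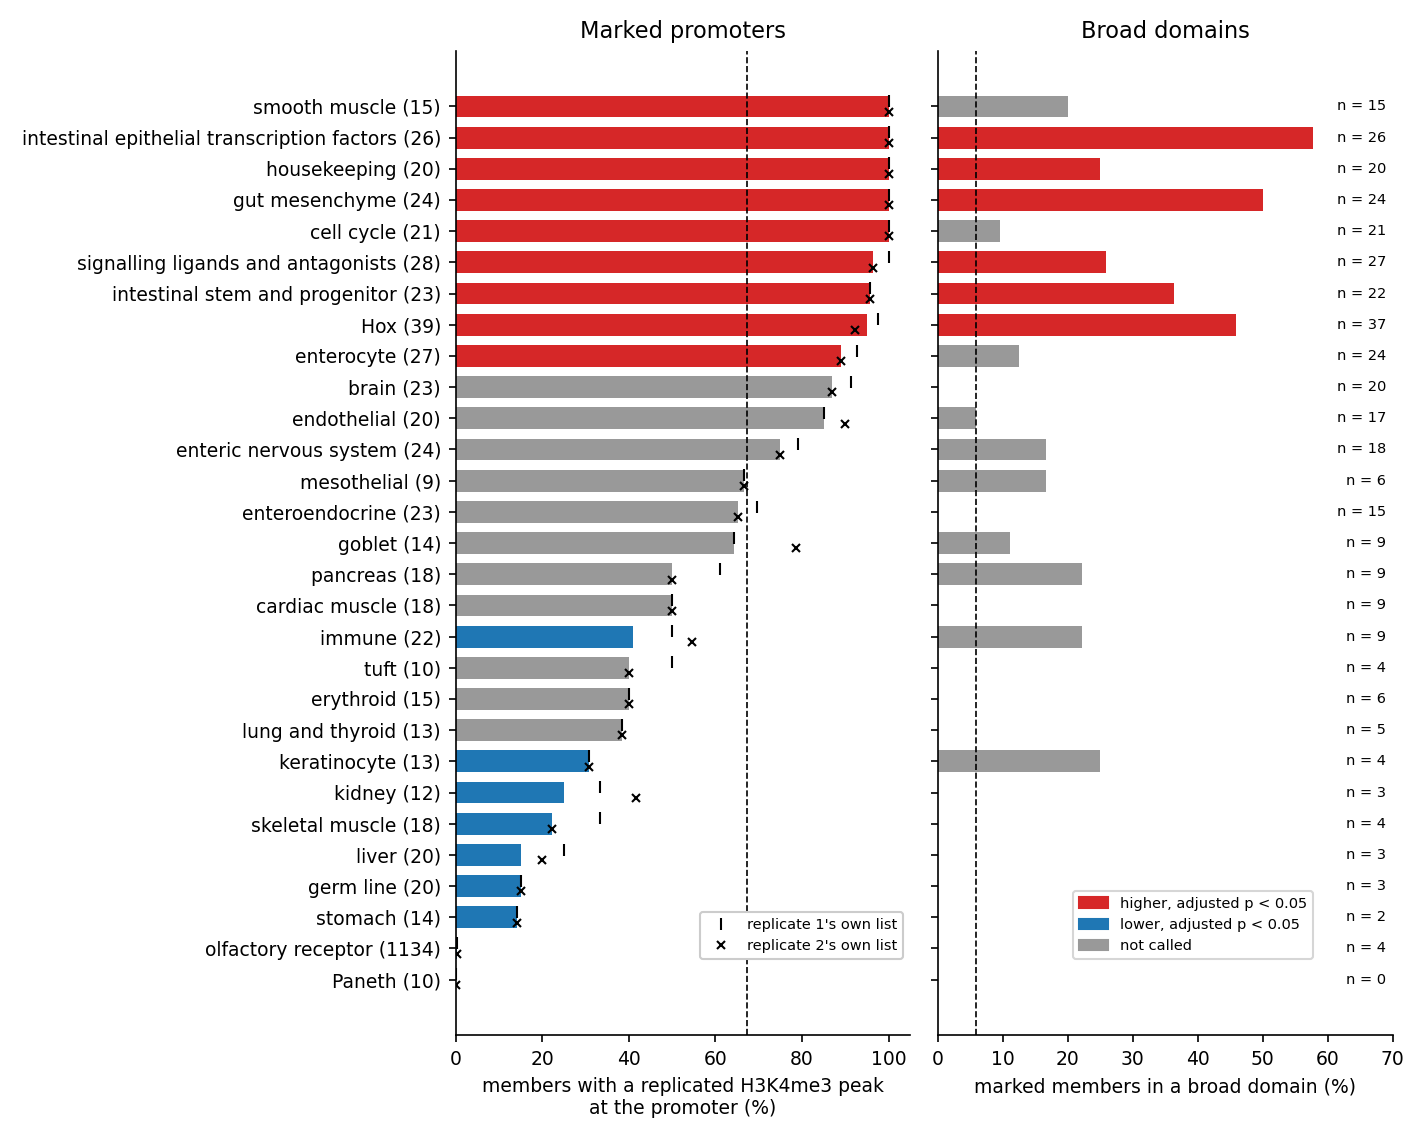
Share of each list's members (number in brackets) with a replicated H3K4me3 peak at the promoter (left, %) and share of the marked members in a broad domain (right, %, n marked). Dashed lines show all protein-coding genes (67.3%, left) and all marked genes (right), and symbols on the left show each replicate's own list; smooth muscle, mesenchyme, epithelial factor, stem and enterocyte lists reach 88.9% or more, and the Paneth list is at 0.

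The epithelial transcription factors and the gut mesenchyme genes also carried broad domains more often than other marked genes. Peaks less than 1000 bp apart were joined, and the widest 5% of the 14422 domains at promoters, those over 4561 bp, were called broad. They covered 857 of the 14714 marked genes. Of the 26 intestinal epithelial transcription factors, 15 were broad (57.7%, against 5.73% of other marked genes, adjusted exact p = 3.2e-11), and of the 24 gut mesenchyme genes 12 were (50%, adjusted exact p = 1.9e-08). The domain at Foxf1, a forkhead factor of the gut mesenchyme, was 18559 bp wide, on chromosome 8 from 121073051 to 121091609 (mm10). It covered the whole gene (121084386 to 121088144) and the 5' end of Fendrr, a long noncoding RNA gene on the opposite strand. The Cdx2 domain was 10633 bp wide, on chromosome 5 from 147299099 to 147309731, and spanned the gene (147300805 to 147307270) on both sides. Ptch1 had a domain of 18245 bp on chromosome 13 from 63555802 to 63574046. Other members, picked for their breadth after the values were seen, were the epithelial factors Foxa1 (16067 bp), Gata4 (13434 bp) and Gata6 (12100 bp) and the mesenchymal factors Nkx2-3 (13007 bp), Hand2 (12164 bp) and Tcf21 (11117 bp). The Shh domain was 9404 bp wide and that of Vil1 5281 bp.

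**Figure D2:**
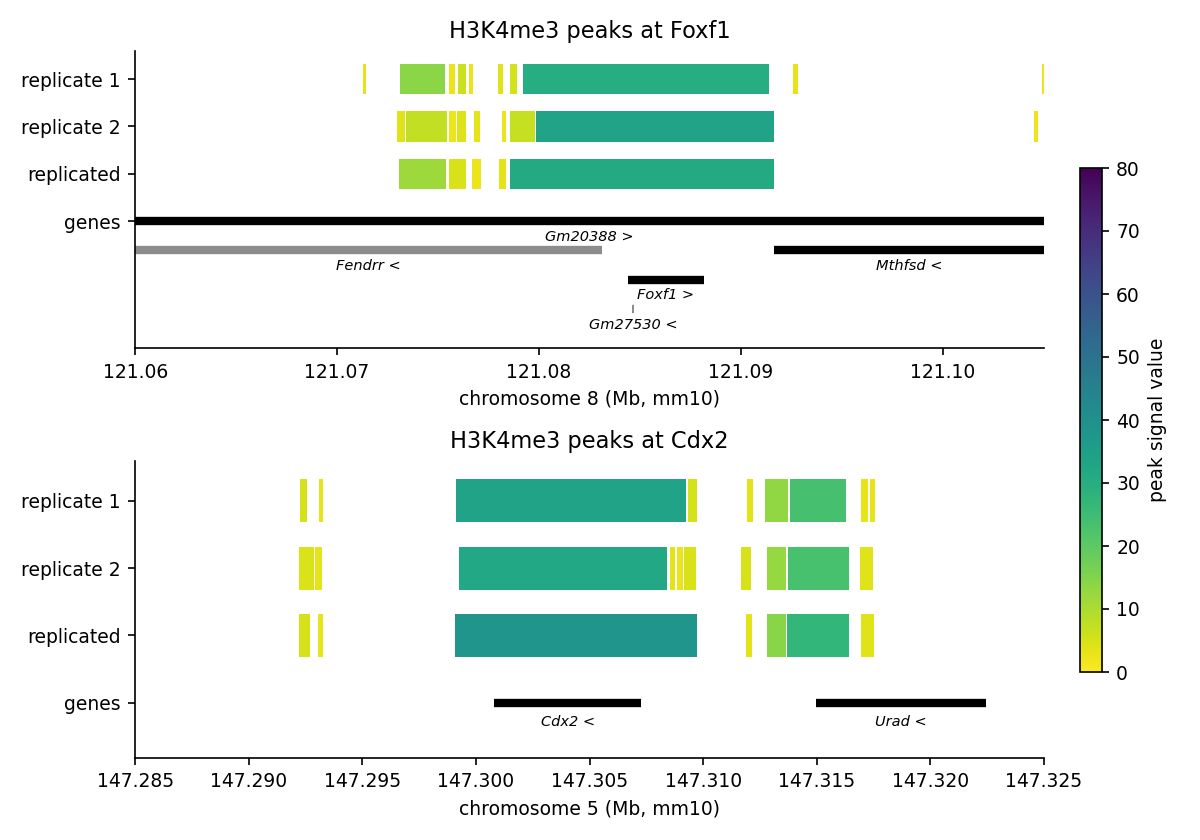
H3K4me3 peaks around Foxf1 (top) and Cdx2 (bottom), with position in Mb of mm10 on the horizontal axis and a row for each replicate's own peaks, the replicated peaks and the annotated genes (black protein-coding, grey noncoding, arrowheads giving the strand). Colour gives the peak signal value; the main Foxf1 peak had 30.6 in replicate 1 and 33.7 in replicate 2, and the main Cdx2 peak 33.6 and 32.

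Broad domains were also more frequent at Hox genes (17 of 37 marked, 45.9%, adjusted exact p = 6.5e-11), stem and progenitor genes (8 of 22, adjusted exact p = 0.00014), signalling genes (7 of 27, adjusted exact p = 0.0039) and housekeeping genes (5 of 20, adjusted exact p = 0.023). None of the 20 marked brain genes was broad, and both gut lists differed from that list when tested against it (adjusted exact p = 2.8e-05 for the epithelial factors and 0.00017 for mesenchyme, Fisher's exact test, 5 list contrasts chosen after the data were seen). The 17 broad Hox genes lay in 9 domains, and the test counted each gene of a shared domain. The Hox call ended when peaks were not joined (16.2%, adjusted exact p = 0.10). The housekeeping call ended with -log10 q of at least 10 (20%) and among genes with a high promoter CpG ratio (21.4%), where the signalling call ended too (33.3%, adjusted exact p = 0.070). Smooth muscle genes, at 3 of 15, passed the threshold with the widest 10% of domains (73.3%), without replicate 1 (33.3%) and with -log10 q of at least 10 (33.3%). Enterocyte genes, at 3 of 24, passed it without replicate 1 (25%), and enteric nervous system genes, at 3 of 18, without replicate 2 (26.3%).

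The widest domain of all lay in the Hoxb cluster. It ran for 31562 bp on chromosome 11 from 96298094 to 96329655 and met the starts of Hoxb3, Hoxb4, Hoxb5 and Hoxb6. The next, 24040 bp on chromosome 6 from 52157444 to 52181483, met Hoxa1 and Hoxa2, and was followed by Meis2, a partner of Hox proteins, with 20693 bp on chromosome 2. Of the 39 Hox genes, which set position along the body axis, 37 were marked (adjusted exact p = 0.00027). Hoxd12 had no peak in any list, Hoxc11 only one in replicate 1's own list, and Hoxb1 a replicated peak but none in replicate 2's own list. Signal was 43.7 ± 3.1 at Hoxa1 and 37.9 ± 6.7 at Hoxb2, and 3.51 ± 0.05 at Hoxc12. Over the 36 genes with a signal in both replicates, the median was 25.3 for the 22 genes of paralogue numbers 1 to 8 and 8.25 for the 14 genes of numbers 9 to 13. Hoxb3 differed most between replicates in the cluster with the widest domain, with 23.0 and 5.67. Its strongest replicated peak (22.7, from 96340298 to 96342927) lay outside that domain.

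**Figure D3:**
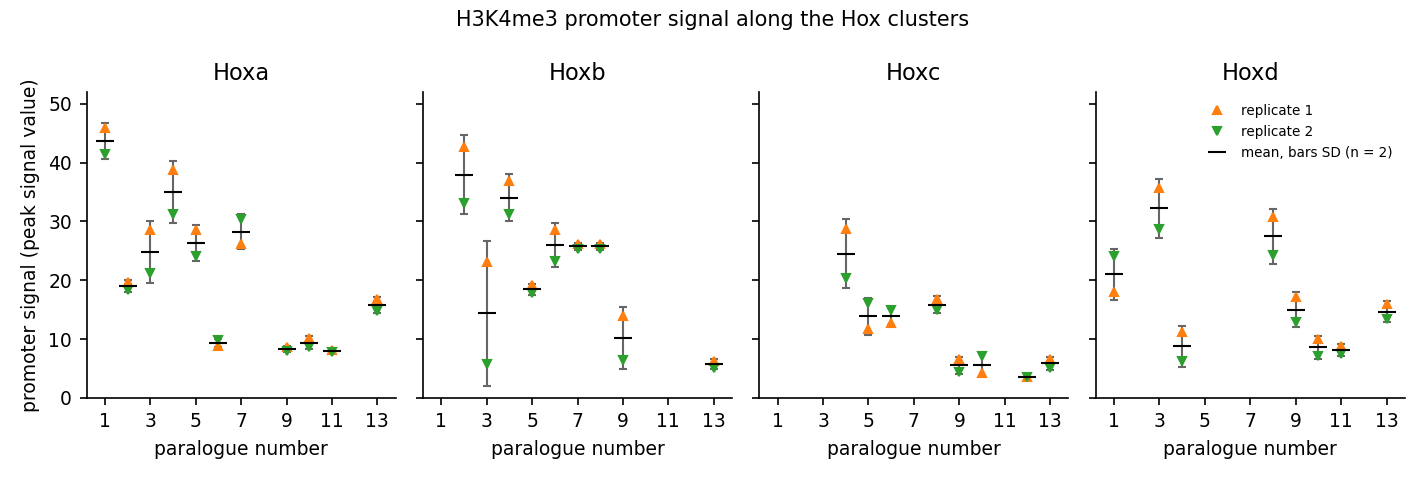
Promoter signal (peak signal value) against paralogue number for the Hox genes of the 4 clusters with a peak in both replicates' own lists. Triangles are replicates, dashes means and bars SD (n = 2); values at numbers 1 to 8 (median 25.3) lie mostly above those at 9 to 13 (median 8.25).

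The highest promoter signals of all genes were 67.5 ± 10.6 at the cytoskeletal actin gene Actg1 and 66.5 ± 7.2 at the chaperone gene Hsp90ab1, and the median over marked genes was 39.6. Each list's median was set against 10000 random lists of as many marked genes. The housekeeping median, 49.1, lay at percentile 99.6, the cell cycle median, 41.6, at 66.4 and the stem and progenitor median, 35.6, at 19.4. Of 20 lists with at least 5 marked members, 16 lay below the 2.5 percentile, including the epithelial factors (25.7, percentile 0.21), mesenchyme (28.0, percentile 1.0), smooth muscle (15.5, percentile 0.030) and enterocyte genes (8.90, percentile 0). Against random lists matched on promoter CpG class, 11 lists lay below 2.5, the enterocyte list lay at 2.5, smooth muscle at 17.3, and the housekeeping list fell to 97.1. With the value of the replicated list, housekeeping lay at 96.1 and the stem and progenitor list at 56.1.

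Marking followed promoter CpG content closely. The CpG ratio, the observed count of CpG over that given by the C and G content of the window, was low (under 0.35) for 7829 genes, of which 17.2% were marked. It was middle for 7604 genes (92.1% marked) and high (over 0.65) for 6420 genes (99.2% marked). Median signal was 11, 35.7 and 46.2 in the 3 classes. Within the low class, 5 lists stood above the other genes, all of cells of the gut wall and epithelium. All 8 smooth muscle genes (adjusted exact p = 1.2e-05), all 7 epithelial transcription factors (adjusted exact p = 5.7e-05), all 5 mesenchyme genes (adjusted exact p = 0.0017), 18 of 20 enterocyte genes (adjusted exact p = 5.4e-11) and 6 of 9 endothelial genes (adjusted exact p = 0.013) were marked, by Fisher's exact test within the class with adjustment over 79 tests. The housekeeping, cell cycle, stem and progenitor, signalling and Hox lists, called higher over all genes, were not called in any CpG class. Nearly all their members lay in the middle and high classes, where 92.1% and 99.2% of all genes were marked. There even a fully marked list of their size could not be called higher. These tests therefore cannot decide whether CpG content accounts for their calls. The shares were near those of the class. In the middle class 19 of 20 Hox genes and 14 of 15 signalling genes were marked, against 92.1% of other genes. In the high class 18 of 19 Hox genes were, against 99.2%. The housekeeping, cell cycle and stem and progenitor members of both classes were all marked. Their calls over all genes thus do not show marking beyond that of their CpG class. In the low class, 2 of 18 liver genes, none of 11 skeletal muscle genes and 2 of 11 cardiac muscle genes were marked. Enterocyte and liver genes differed (adjusted exact p = 7.5e-06, Fisher's exact test), as did smooth and skeletal muscle genes (adjusted exact p = 2.8e-05) and smooth and cardiac muscle genes (adjusted exact p = 0.00071). These comparisons belong to the 5 list contrasts chosen after the data were seen. Of the middle class, 1 of 9 germ line genes was marked, against 92.2% of other genes (adjusted exact p = 2.4e-07). Ddx4 and Figla were among the unmarked ones. Within CpG classes, the germ line and olfactory receptor lists were the only ones called lower after adjustment. In the low class, small lists could not be called lower even with no gene marked, as for stomach (0 of 12, exact p = 0.24 before adjustment). For such lists the lack of a call does not show that they were marked as often as other genes.

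**Figure D4:**
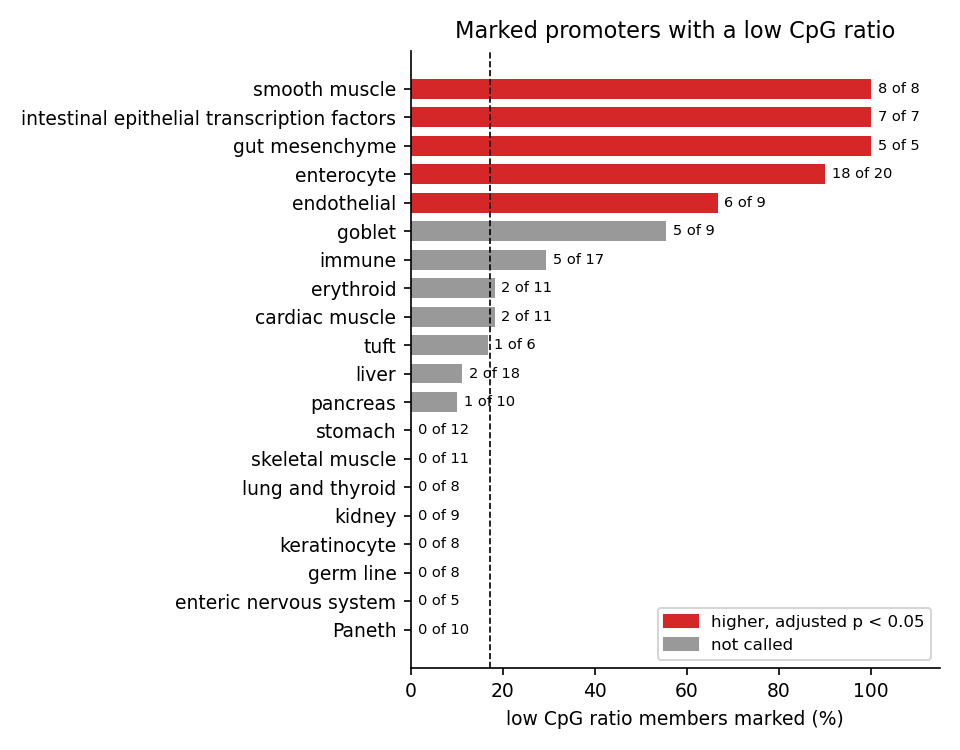
Share of members with a low promoter CpG ratio (under 0.35) that had a replicated peak, for lists with at least 5 such members, the olfactory receptors left out. The dashed line is the share of all genes of the class (17.2%); smooth muscle, epithelial factor, mesenchyme, enterocyte and endothelial lists lie above it by Fisher's exact test, and 8 lists are at 0.

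By position, 58.2% of the replicated peaks on the assembled chromosomes lay at promoters of protein-coding genes (16255 peaks), 22.4% elsewhere in such genes (6263) and 19.3% between genes (5392). The same intervals shuffled within chromosomes gave 4.23%, 39.0% and 56.7%. Promoter peaks were wide and strong, with a median width of 1704 bp and a median signal of 39.6, against 463 bp and 4.75 in gene bodies and 552.5 bp and 6.21 between genes. They held 79.2% of the covered bases.

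The replicates shared nearly all of their strong peaks. Of replicate 1's peaks, 81.9% overlapped a peak of replicate 2, and of replicate 2's peaks 85.1% overlapped one of replicate 1, against 2.74% and 2.73% for shuffled intervals. The 6163 and 5154 peaks not shared were weak and narrow, with median signals of 3.23 and 3.2 and widths of 222 and 211 bp. In the lowest of 4 equal groups by signal 43.3% and 53.2% were shared, and in the highest 100% of both. At promoters the shares were 94.2% and 95.7%, and in gene bodies 65.3% and 69.6%. A promoter peak was present in both own lists for 14678 genes, in replicate 1 only for 172 and in replicate 2 only for 117. Across those 14678 genes, which are not independent replicates, promoter signal correlated with Spearman's rho of 0.899 and, on the log2 scale, Pearson's r of 0.955. Replicate 1 was higher at 83.0% of the genes, with a median ratio of 1.14 and an SD of the log2 ratio of 0.28. The replicate values were close at Cdx2 (33.6 and 32), and further apart at Myod1 (3.33 and 2.66), Fabp2 (7.04 and 12.9) and Ret (38.7 and 21.6). The largest value at a promoter may come from different peaks in the 2 replicates, which was not checked.

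**Figure D5:**
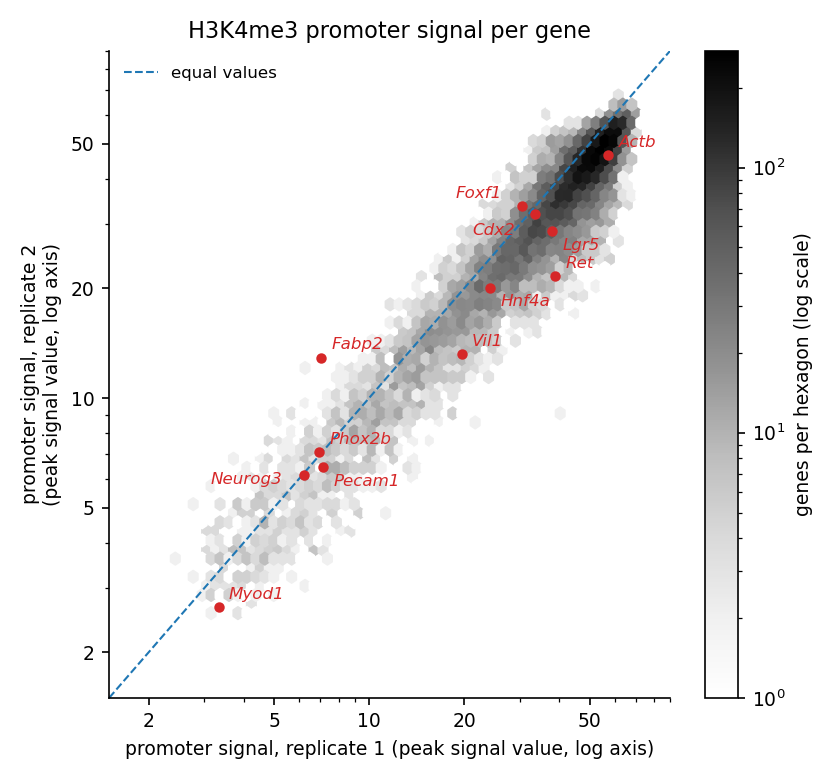
Promoter signal (peak signal value, log axes) in replicate 1 and replicate 2 for the 14678 genes with a peak in both own lists, with shading for the number of genes and a dashed line of equal values. Named genes are in red; most genes lie below the line, 83.0% being higher in replicate 1.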

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

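The replicated list held 12 peaks on scaffolds outside the assembled chromosomes, which the comparisons above did not use. They drew attention as signal in data left out of the main measurement. By the annotation of the primary assembly, 2 of them lay at the starts of Vamp7 and Tmlhe on the X scaffold GL456233, with signal values of 38.3 and 26.9 in the replicated list. The strongest, with 43.2, lay at the start of CAAA01118383.1 on the chromosome 4 scaffold GL456216. No technical or biological explanation was tested for these peaks.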

How the results depend on the processing

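The alternatives were set before their results were seen, except peaks that meet no other gene's promoter and broad domains among genes of high promoter CpG ratio only, which were chosen after seeing the data. The number of marked genes lay between 12243 and 14886 in the alternatives, against 14714. Of 319 pairs of list and setting for marking, 285 kept their direction and side of the threshold, and of 194 pairs for broad domains 172 did. Many lists are small, so a change of 1 or 2 genes can move a call, and the cause of each change below was not tested. Read depth is unknown, so its effect on weak peaks could not be measured.

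For marking, as percent of members, a window of 500 bp gave enterocyte 85.2 (no longer called), lung and thyroid 30.8 and cardiac muscle 38.9 (both now lower). A window of 2000 bp gave immune 45.5 (no longer called), erythroid 40 (now lower) and goblet 85.7 (uncalled, now above other genes). The gene's 5' end only gave enterocyte 74.1 (not called), lung and thyroid 23.1 (now lower) and enteroendocrine 65.2 (uncalled, other direction). Enterocyte also lost its call at -log10 q of at least 10 (77.8), signal of at least 4 (81.5) and overlap of at least 200 bp (85.2). The pooled list gave immune 54.5 (not called), erythroid 40 (now lower), and goblet 78.6 and enteroendocrine 69.6 (uncalled, other direction). Without replicate 1 or without replicate 2, immune ranged from 50 to 54.5 (not called in either) and erythroid was 40 in both (now lower). Without replicate 1, kidney was 41.7 (not called) and goblet 78.6 (uncalled, other direction). Without replicate 2, lung and thyroid was 38.5 (now lower), brain 91.3 (now higher, against 86.96 without replicate 1) and enteroendocrine 69.6 (uncalled, other direction). With only peaks that meet no other gene's promoter, housekeeping 80, immune 40.9, kidney 25 and keratinocyte 30.8 were no longer called, endothelial 85.0 and brain 82.6 were now higher, and goblet 64.3, enteroendocrine 65.2 and mesothelial 66.7 were uncalled in the other direction.

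For broad domains, as percent of marked members, peaks not joined gave Hox 16.2 (no longer called), and enterocyte 4.17 and goblet 0 (uncalled, other direction). Joining under 3000 bp gave enteroendocrine 6.67, cardiac muscle 11.1 and brain 5 (uncalled, other direction). The widest 10% gave smooth muscle 73.3 (now higher), and brain 10 and tuft, skeletal muscle and olfactory receptor 0 each (uncalled, other direction). Without replicate 1, enterocyte was 25 and smooth muscle 33.3 (both now higher), and without replicate 2 enterocyte was 4.00 (uncalled, other direction) and enteric nervous system 26.3 (now higher, against 16.7 without replicate 1). At -log10 q of at least 10, housekeeping was 20 (no longer called) and smooth muscle 33.3 (now higher). With high promoter CpG ratio only, housekeeping 21.4 and signalling 33.3 were no longer called, and cell cycle, enteroendocrine and cardiac muscle were 0 each (uncalled, other direction).

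Of the values without a test, overlap of the replicates' peaks was 77.4% (replicate 1) and 81.3% (replicate 2) over at least 50% of the peak, 88.6% for replicate 2 at -log10 q of at least 2, 93.6% and 97.4% at -log10 q of at least 10, and 96.0% and 97.6% with the same number of top peaks. Spearman's rho was 0.945 with -log10 p and 0.948 with the sum of signal times width, the median log2 ratio 0.28 and 0.25 with these and -0.034 with values divided by the replicate's median, and the SD of the log2 ratio 0.38 with signal times width. Lists above the upper percentile limit numbered 0 with random lists matched on promoter CpG class and 0 with the value in the replicated list, against 1. Peaks at promoters were 64.5% with a window of 2000 bp, 63.8% with all annotated genes, 69.2% at -log10 q of at least 10, and 51.4% to 52.2% without a replicate. With a window of 500 bp, 11.8%, 80.9% and 98.9% of genes of low, middle and high CpG ratio were marked.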

Other observations

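The gene families, noncoding genes and genes outside the fixed lists in this part were chosen after the data were seen. So were the tests of brain and Hox genes against the gut lists, of one scale factor, of other-organ genes and of the direction along the Hox clusters. The other tests were set before their own results were seen, but for patterns already seen in these data.

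Large gene families differed widely in marking. All 78 mitochondrial ribosomal protein genes were marked, as were 88 of 98 genes whose symbol starts with Rpl or Rps and a digit. Other genes were marked at 67.2% in each case (adjusted exact p = 7.6e-14 and 5.2e-07, Fisher's exact test over 10 families taken by symbol). The Rpl and Rps rule takes in any gene so named, ribosomal protein or not, and leaves out symbols without that digit, such as Rplp0. Zinc finger genes named Zfp were marked at 346 of 394 promoters (adjusted exact p = 9.0e-21) and solute carrier genes at 286 of 371 (adjusted exact p = 5.4e-05). Replication-dependent histone genes were marked at 58 of 67 (adjusted exact p = 0.00057), with a low median signal of 16.0. Of these 58 genes, 29 shared all their peaks with another gene's promoter window, as did 31 of the 78 mitochondrial ribosomal protein genes. That held for 16.8% of all marked genes. It held for 17 of the 88 Rpl and Rps genes, 33 of the 346 Zfp genes and 26 of the 286 solute carrier genes. Other families were marked less often. Cytochrome P450 genes were marked at 30 of 100 promoters (adjusted exact p = 5.8e-14) and clustered protocadherin genes at 25 of 57 (adjusted exact p = 0.00035). Marked were 1 of 331 vomeronasal receptor genes (adjusted exact p = 5.6e-160), 0 of 57 keratin-associated protein genes (adjusted exact p = 8.7e-28) and 0 of 42 beta-defensin genes (adjusted exact p = 9.0e-21). The families were not compared within promoter CpG classes, so a part played by CpG content stays open.

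Beyond protein-coding genes, 2560 of 10150 long noncoding RNA genes (25.2%) had a replicated peak at the 5' end, and 886 had one outside every protein-coding promoter window. Promoter signal was 43.8 ± 6.8 at Malat1, 32.1 ± 4.4 at the imprinted Kcnq1ot1, 19 ± 2.6 at Meg3 and 17.7 ± 4.9 at H19. Hotair and Hottip, which lie in Hox clusters, were unmarked. Xist, the RNA that silences an X chromosome in females, had 16.4 ± 0.7, with 16.9 in replicate 1 and 15.9 in replicate 2, in pools labelled as of both sexes. The 4 marked genes of the Y chromosome were all higher in replicate 1: Ddx3y (18.7 and 11.3), Uty (19 and 9.04), Eif2s3y (13.1 and 11.3) and Kdm5d (14 and 6.46). Among the widest domains outside the fixed lists were those of Tbx2 (15841 bp), Meis1 (14336 bp), Nr2f2 (13310 bp) and the imprinted growth factor gene Igf2 (12326 bp). Of the replicated peaks, 10104 (36.2%) lay away from the start of every annotated gene, with a median signal of 5.11.

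Broad domains concentrated at epithelial transcription factors and gut mesenchyme genes, 27 of 50 marked members. High CpG content alone is argued against, since within genes of high promoter CpG ratio 16 of 26 members were broad against 8.07% of other genes (p = 9.8e-12, Fisher's exact test). Joining of neighbouring peaks is argued against as well, since with peaks not joined 27 of 50 members were among the widest (exact p = 6.2e-20). A property of developmental regulators in general stays open, since the brain list had 0 of 20 broad (exact p = 6.6e-06) but the Hox list 17 of 37 (exact p = 0.52 against the 2 gut lists), which fell to 6 of 37 with peaks not joined (exact p = 0.00035). Broad domains may follow regulators in use in this tissue, a hypothesis left open as no expression data were analysed here.

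Promoters of other organs' genes were marked in part, and promoter CpG content may account for most of the presence of peaks, but not for their signal. Of the 149 members of 9 such lists, 1, Pax6, also stands in another list. Of the members with a middle or high CpG ratio 90% were marked (54 of 60), and of those with a low ratio 5.62% (5 of 89). The difference was 84.4 percentage points. Signal was low, however. The 53 marked members of middle or high ratio with a signal in both replicates had a median of 13.5, against 41.5 for 13304 other such genes. Admixed cells of those organs would bring the mark also to the low-ratio genes active in them at this age, which may include abundant transcripts such as Alb. Which members are active there was not examined, so a low share is limited evidence against admixture. The share of all low-ratio members, 5.62% (95% exact interval 1.85% to 12.6%), was below that of other genes of the class (17.3%) and of low-ratio enterocyte genes (90%). A small admixture of single organs stays open, as the 5 marked genes, named after their values were seen, were Actc1 and Myl7 of cardiac muscle (2 of 11), Ttr and Nr1i3 of liver (2 of 18) and Bhlha15 of pancreas (1 of 10).

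Along the Hox clusters, promoter signal may fall from low to high paralogue numbers. Pearson's r across 36 genes, which are not independent, was -0.68. Spearman's rho across them was -0.68 (p = 4.0e-05 by permutation within clusters), with -0.71 and -0.63 in the single replicates. It was -0.71 without the 2 genes farthest from the median number, -0.62 with the gene's 5' end only, and between -0.64 and -0.76 within each cluster. Promoter CpG content is argued against, since the CpG ratio went the other way, with a rho of 0.38 (p = 0.014). Starts shared between neighbouring genes and the position of the sampled segment along the gut were not tested and stay open.

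Promoter signal was higher in replicate 1 by a median log2 ratio of 0.19. In 4 equal groups of genes from lowest to highest signal, the medians were 0.198, 0.229, 0.197 and 0.169, each within 0.034 of that. One scale factor between the 2 peak lists would give equal medians. The values are near that but not equal, and their differences were not tested. For different cell composition of the 2 tissue pools, 0 of 20 lists had a median ratio outside random lists matched on signal after adjustment (0 of 20 also at an unadjusted p under 0.05), and the housekeeping list had a median of 0.19. Small lists such as the endothelial one (random range 0.01 to 0.38 for 17 genes) leave smaller shifts undetected. These lists do not cover the share of male embryos in each pool, which was not tested, and the Y chromosome genes above all differed by more than the median ratio of 1.14, Eif2s3y the least.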
